A study of Mus musculus with 6 samples.

How the data were processed

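RNA sequencing was used to measure gene expression in 6 cultures of B16F10 cells, a mouse melanoma line of C57BL/6 origin, grown as spheroids in Matrigel, a basement membrane extract. Per the labels, 3 cultures received BMP2 at 100 ng/ml and 3 received PBS, each for 10 days, and the experiment was carried out 3 times, so that each of the 3 batches holds 1 culture of either kind. Libraries were made with an Illumina TruSeq kit, per the labels' protocols. The strand setting of the quantification is not given in the sources used here.

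The authors deposited a table of estimated counts per gene, which need not be whole numbers. Reads were assigned with kallisto 0.44.0 and the mouse build was GRCm38.p6, per the submitters' processing notes. The annotation release, and how transcript values were brought to the level of genes, are not given in the sources used here. Kallisto divides reads that match several transcripts between them by likelihood, so a gene with near-identical copies can gain or lose reads to those copies. The table names 34981 Ensembl genes, and 34679 of these were matched by identifier to GENCODE release M21 on GRCm38 for symbols, positions, length and GC content, while 302 were not matched. No row of the table lacked a gene. Values were rounded to whole numbers before the count tests. Totals per library lay between 27821900 and 36856500 estimated counts, and 3 counts in a library correspond to about 0.103 CPM at the lowest total after scaling. Intervals and bounds from counts treat each group as a whole, so they leave out variation between cultures. They also take estimated counts as counted reads, which carry no molecular identifiers, and leave out error in dividing reads between copies. The columns named for controls were matched to the samples titled as untreated, which the protocol describes as given PBS.

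Genes were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, after filtering on low counts with the default of the package and scaling by trimmed mean of M values (TMM). The model held the treatment alone, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05, and 12929 genes were tested. Values per group are TMM-scaled CPM (counts scaled to library size), given as mean ± SD over 3 libraries. Log2 fold changes are BMP2 minus PBS, with a standard error (SE) worked back from the fold change and the F statistic of the test. For genes near 0 counts in 1 group, this SE should not be read as the uncertainty of the fold change. The labels state that the replicate number marks a shared batch. Deviations from the group means correlated at 0.51, 0.25 and 0.52 across genes between the BMP2 and PBS libraries of batches 1, 2 and 3, against -0.51 to 0.03 for libraries of different batches. Deviations sum to 0 within a group, so positive values within batches push those between batches down, and the latter add no separate evidence. Given the shared batches, the model with batch as a block was fitted as well, and its values are printed where they change a call. It leaves 2 residual degrees of freedom, against 4 without the block.

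The 36 gene lists were written before the data were examined, as were the model, the alternatives and the rule for naming genes. A list was tested if it had at least 5 tested genes, which 34 lists had, with camera of limma 3.58.1 at a preset correlation of 0.01 and adjustment over the lists. Camera with an estimated correlation was an alternative, and fry was run as a test of the list against no change. The rule named 11 genes in any case (Id1, Id2, Id3, Smad6, Smad7, Bambi, Bmp2, Mitf, Tyr, Dct and Sox10). It added the 10 strongest genes in either direction that moved the same way in all 3 batches, filled by smallest unadjusted p where fewer than 10 passed, without predicted genes and pseudogenes. It also took up to 3 members with the smallest unadjusted p from each list that passed and from 8 lists chosen in advance. A few genes that the rule names are not reported here. Members of the lists that passed with the block and not without it, the pseudogene copies and the other members given in the closing section were chosen after their values were seen.

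The other alternatives were no filter on low counts, a filter at a mean of 100 counts, the size factors of DESeq2, quantile normalization with limma-trend, the Wald test of DESeq2 1.42.0, a smooth correction for GC content and gene length with the block, and leaving out each library. Summing of near-identical genes, the same alternatives with the block, and leaving out each batch were added after the data were seen. For the summing, genes were joined where at least 80% of the 31-mers of the smaller gene occurred in the other, counted over annotated transcripts with Python 3.11.15, which gave 1129 families of 2958 genes. The scripts were tested on simulated counts for 12689 genes with the means and library sizes of these samples, in which 100 genes changed by 2-fold and 100 by 4-fold. The means held the batch differences, the spread was that of the blocked fit, and changed genes were not drawn among the lowest counts. The simulation thus followed the model with the block and cannot decide between the 2 models. The model without the block recovered 0% of the 2-fold and 58% of the 4-fold changes with 0 false calls among 58. The model with the block recovered 63% and 98%, with 9 false calls among 170, or 5.29%.

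Within groups, log2 CPM correlated at 0.934 to 0.979 between libraries across genes, and the counts of each pair differed far beyond sampling noise, with a chi-square per gene of 68.6 to 244. No library was therefore counted as a repeat of another.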

Results

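The series measured messenger RNA in B16F10 mouse melanoma spheroids kept in Matrigel for 10 days with BMP2 (100 ng/ml) or PBS, with 3 libraries per group. BMP2 is a secreted ligand of the transforming growth factor-beta superfamily that acts through receptor-activated SMAD proteins. The comparison asks how the transcriptome of the melanoma cells differs when the ligand is present. The BMP2 libraries of batches 1, 2 and 3 held 27821900, 34571400 and 36856500 estimated counts, and the PBS libraries 35274700, 36494000 and 32311900. The most abundant gene was Gapdh, a glycolytic enzyme, at 2.45% to 4.88% of the counts, and genes encoded in mitochondrial DNA took 4.12% to 4.62%. The library PBS 1 stood apart on the first principal component, which held 50.0% of the variance, at -79.7 against -16.8 to 55.5 for the others. PBS 1 also had the lowest TMM factor, 0.872, and the highest share of counts at pseudogenes, 2.81% against 1.83% to 2.37%.

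Of the 18 tested genes in the list of known BMP targets, 10 were higher with BMP2 in all 3 batches and 4 were lower in all 3. Over all tested genes, 22.8% were higher and 21.1% lower in all 3 batches, so the same direction in each batch is weak evidence for a single gene. With batch as a block, Id2, an inhibitor of basic helix-loop-helix transcription factors, rose from 59.4 ± 24.2 to 447 ± 266 CPM (SD, n = 3), a log2 fold change of 2.80 (SE 0.23). Smad9, a receptor-activated SMAD, rose by 3.69 (SE 0.35), from 1.19 ± 0.21 to 17.0 ± 9.4 CPM. Atoh8, a transcription factor, rose by 5.74 (SE 0.56), and Nog, which encodes the secreted BMP antagonist noggin, by 7.61 (SE 0.75), from 11 and 5 estimated counts over the PBS libraries. Their edgeR quasi-likelihood Benjamini-Hochberg adjusted p values were 0.0152 for Id2 and 0.0241 for Smad9, Atoh8 and Nog with the block, and 0.21, 0.0802, 0.19 and 0.21 without it. Of these 4 genes, Id2, Smad9 and Atoh8 also passed with each batch left out, while Nog had an adjusted p of 0.134 without batch 2, at a log2 fold change of 6.08. Fits without a batch leave fewer residual degrees of freedom than the 2 of the full blocked fit, so a pass there is no firm check.

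Id1, Id3 and the inhibitory SMAD gene Smad6 had log2 fold changes of 3.28 (SE 0.71), 3.80 (SE 0.78) and 3.76 (SE 0.64) without the block and were higher in each of the 3 batches, but did not pass over all genes in either fit (edgeR adjusted p 0.131, 0.117 and 0.0665 with the block). Their log2 differences were smallest in batch 1, at 1.35, 2.26 and 1.73, and largest in batch 3, at 5.78, 7.11 and 4.91. Those of Id2 varied less, at 2.51, 2.45 and 3.45 in batches 1, 2 and 3. Smad7, the other inhibitory SMAD gene, was at 10.7 ± 8.0 against 5.36 ± 0.99 CPM and was higher in 2 of the 3 batches (edgeR adjusted p 0.883). Bambi, a BMP pseudoreceptor, had a log2 fold change of -0.15 (SE 0.36), which became 0.35 without PBS 1. Transcripts of Bmp2 itself had 0 counts in all 6 libraries. Of the 18 genes in the list, 0 passed over all genes without the block and 4 rose with it. Adjusted over the list alone, 8 rose and 1 fell in either fit. The gene that fell was Runx2, a regulator of osteoblast differentiation, with a log2 fold change of -1.97 with the block. The median log2 fold change of the list was 0.81, with medians of 0.72, 0.82 and 0.73 in batches 1, 2 and 3, and its camera adjusted p was 1.31e-05, or 0.000441 with the block. These batch medians do not show the spread of single members between batches, such as that of Id1, Id3 and Smad6. The call was lost at adjusted p = 0.882 with an estimated correlation, and at 0.837 with the block. The median was 0.24 without BMP2 replicate 2, 1.36 without BMP2 replicate 1 and 2.10 over the genes left by the stricter count filter.

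**Figure D1:**
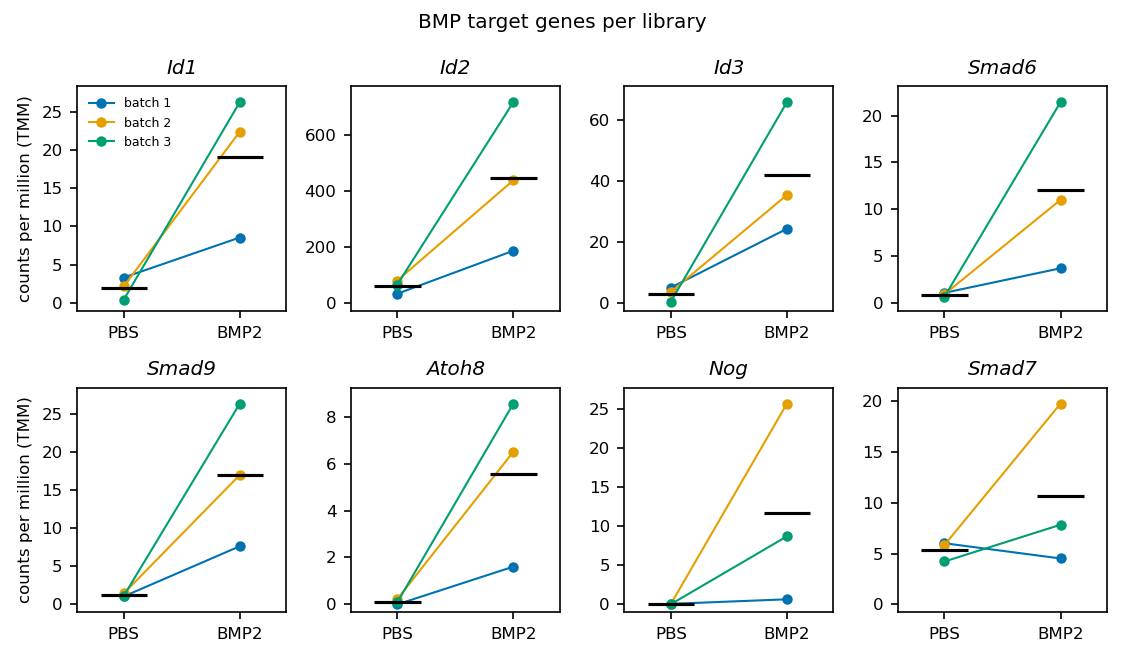
TMM-scaled CPM of 8 BMP target genes in each library, with lines joining the PBS and BMP2 cultures of a batch and black bars at the group means (n = 3). Id2 was at 447 on average with BMP2 and 59.4 with PBS, and Smad7 was higher with BMP2 in 2 of the 3 batches.

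Of 26 tested genes of the pigmentation list, which act in melanin synthesis, melanosome transport and the melanocyte lineage, 22 were higher with BMP2 in all 3 batches and 2 were lower in all 3. Mlph, which links melanosomes to the myosin motor, rose by a log2 fold change of 2.05 (SE 0.23) with batch as a block, from 95.1 ± 66.9 to 339 ± 181 CPM (SD, n = 3). Gpr143, a melanosomal receptor, rose by 1.75 (SE 0.15), the ion exchanger gene Slc24a4 by 1.30 (SE 0.17), Rab32, a GTPase of melanosome biogenesis, by 1.12 (SE 0.17), and the melanocyte channel gene Trpm1 by 1.02 (SE 0.13). Tfap2a, a transcription factor of melanocyte development, fell by 1.03 (SE 0.13). The adjusted p values of these 6 genes with the block were between 0.019 and 0.0482 with edgeR, and without the block all were above the threshold (0.355 for Tfap2a to 0.883 for Gpr143). Mitf, the master regulator of the melanocyte lineage, was at 298 ± 29 against 199 ± 9 CPM (log2 fold change 0.58, SE 0.18), and Tyr, the rate-limiting enzyme of melanin synthesis, at 1111 ± 267 against 610 ± 363. The log2 fold changes of Dct, another melanin enzyme gene, and Sox10, a lineage transcription factor, were 0.43 (SE 0.21) and 0.40 (SE 0.35). Mitf, Tyr, Dct and Sox10 did not pass over all genes in either fit (edgeR adjusted p 0.142 to 0.291 with the block).

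Over all genes 0 pigmentation genes passed without the block, while 5 rose and 1 fell with it. Adjusted over the list alone, 0 passed without the block, and 17 rose and 1 fell with it. The median log2 fold change was 0.61, with 0.69, 0.61 and 0.59 in the 3 batches, and the camera adjusted p was 1.91e-07 (adjusted p = 0.882 with an estimated correlation, and 0.511 with the block). Fry as a directional test, which asks for a shift to 1 side, gave adjusted p of 0.559 without the block and 0.0467 with it. For the BMP target list this test gave 0.559 and 0.448. Fry for change in either direction gave adjusted p of 0.193 and 0.00892 for pigmentation, and 0.0231 and 0.0172 for BMP targets. With the block, lists that did not pass camera also passed that test, such as neural crest (0.00892), Notch targets (0.00671) and leukocyte markers (0.00671). Some that passed camera did not, such as hypoxia (0.0777) and ribosomal proteins (0.0924). The test for either direction thus does not single out pigmentation or BMP targets. Without batch 2, only Mlph and Gpr143 of the 6 called pigmentation genes passed, both at 0.0466, and Trpm1 was at 0.0863 without batch 3.

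**Figure D2:**
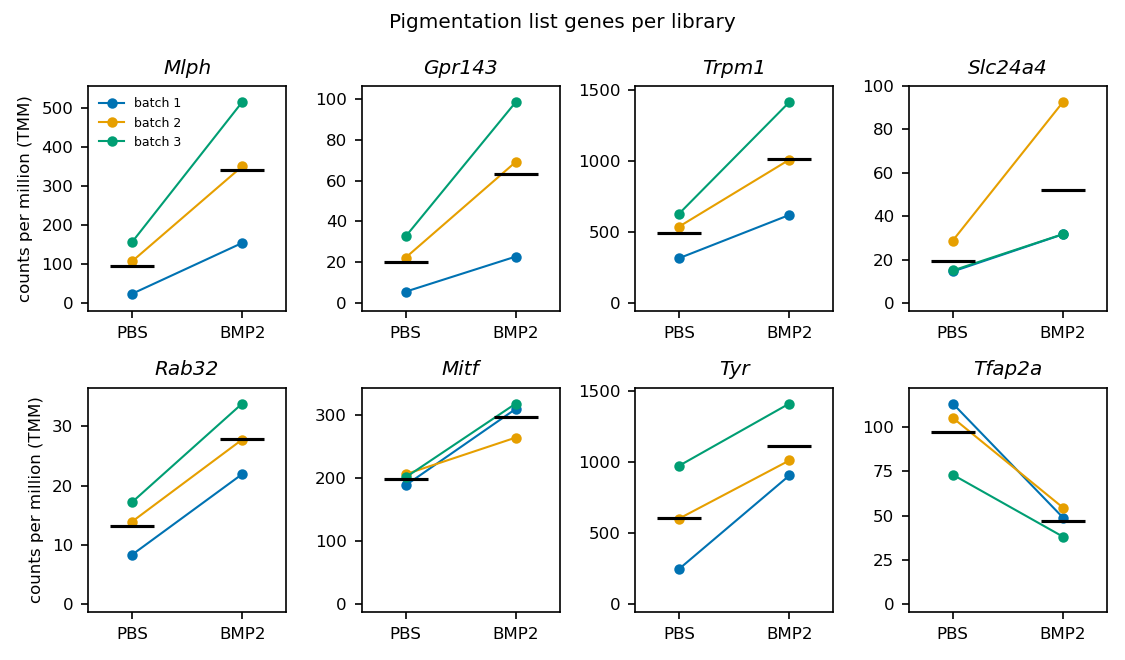
TMM-scaled CPM of 8 genes of the pigmentation list in each library, with lines joining the PBS and BMP2 cultures of a batch and black bars at the group means (n = 3). Mlph was at 339 on average with BMP2 and 95.1 with PBS, and Tfap2a at 47.1 and 97.0.

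Several metabolic and biosynthetic lists had medians below 0 with BMP2 against PBS. In the hypoxia and glycolysis list, 19 of 35 tested genes were lower in all 3 batches and the median log2 fold change was -0.38. Ddit4, a stress-induced inhibitor of mTORC1 signalling, fell by 1.35 (SE 0.20) with the block, and Higd1a, a hypoxia-induced mitochondrial protein gene, fell by 1.20 (SE 0.17). Ankrd37, a hypoxia-responsive gene, was at 18.6 ± 11.5 against 54.2 ± 11.4 CPM and did not pass. In the ribosomal protein list, 35 of 45 genes were lower in all 3 batches and the median was -0.43, and Rpl13 had a log2 fold change of -0.64 (SE 0.28). Rpl3 went the other way and rose by 1.53 (SE 0.21) with the block, although 35.6% of its 31-mers occur in other genes, so that its own level is uncertain. The sum of Rpl3 and its near-identical pseudogene Rpl3-ps1 also rose with the block, by 1.89 (SE 0.25, edgeR adjusted p 0.0364). The cholesterol synthesis list had a median of -0.30, and Lss, which encodes lanosterol synthase, fell by 1.46 (SE 0.15) with the block, while Stard4 and Hmgcs1 had log2 fold changes of -0.34 and -0.51. Nuclear genes of oxidative phosphorylation had a median of -0.19, with -0.43 for Uqcrq and -0.31 for Uqcrfs1. The antioxidant and iron list had a median of -0.27, with 0.14, -0.39 and -0.41 in batches 1, 2 and 3, while the other 4 lists had medians below 0 in each batch. Its members included Gstm1, a glutathione transferase, at -1.20 (SE 0.22), and the ferritin genes Ftl1 and Fth1 at -0.77 and -0.37. Ftl1 shares 54.5% of its 31-mers with other genes and is uncertain.

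Without the block, 0 genes of these 5 lists passed over all genes. With it 2 hypoxia genes and 1 cholesterol gene fell and 1 ribosomal protein gene rose. Adjusted over the list alone with the block, 8 hypoxia, 5 cholesterol and 3 antioxidant genes fell, 1 ribosomal protein gene rose and 0 oxidative phosphorylation genes passed. Camera adjusted p values were 3e-06 for hypoxia, 1.57e-06 for ribosomal proteins, 0.00358 for oxidative phosphorylation, 0.0261 for cholesterol and 0.0402 for antioxidant genes, and for each list adjusted p = 0.882 with an estimated correlation. Fry as a directional test called none of these 5 lists. Its adjusted p values were 0.827 to 0.855 without the block and 0.103 to 0.557 with it. The values moved with single libraries, PBS 1 among them, which stood apart: without PBS 1 the medians were -0.098 for ribosomal proteins (camera adjusted p 0.466), 0.00639 for oxidative phosphorylation (0.879), -0.47 for cholesterol and -0.44 for antioxidant genes, and without PBS 3 they were -0.29 for oxidative phosphorylation, 0.11 for cholesterol (0.811) and -0.17 for antioxidant genes (0.411). The cholesterol median was -0.058 without BMP2 replicate 1 (0.96), -0.23 without BMP2 replicate 2 (0.123) and -0.65 without BMP2 replicate 3, the antioxidant call was lost without BMP2 replicate 1 (0.191) or PBS 2 (-0.16, 0.342), and the hypoxia median was -0.20 without BMP2 replicate 3, with the call kept (0.00672). Leaving out 1 library without the block also breaks a batch pair, and within batches 1, 2 and 3 the cholesterol medians were -0.38, -0.24 and -0.34. Under quantile normalization the medians were -0.18 for ribosomal proteins, with the call kept (0.00363), -0.12 for oxidative phosphorylation (0.137), -0.24 for cholesterol (0.0864) and -0.11 for antioxidant genes (0.134), and the antioxidant call was also lost with no filter (0.075) and with the GC and length correction (0.0631). Without batch 2, the adjusted p of Ddit4, Higd1a, Lss and Rpl3 with the block was 0.0611 to 0.166, and that of Higd1a was 0.0546 without batch 3. The log2 fold changes of Ddit4, Higd1a, Lss and Rpl3 without batch 2 were -1.56, -1.26, -1.55 and 1.42.

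Lists of inflammatory, growth-factor response and mitotic genes also had medians below 0, though those of the immediate-early and G2/M lists were not below 0 in every batch. In the NF-kappaB list of 17 tested genes the median log2 fold change was -0.56, and the subunit genes Relb and Nfkb2 had values of -0.80 (SE 0.22) and -0.73 (SE 0.21) and the chemokine gene Cx3cl1 -1.65 (SE 0.62). Among 34 immediate-early genes of the MAPK pathway the median was -0.65, with 0.20, -0.77 and -0.69 in batches 1, 2 and 3. Jun, a subunit of AP-1, fell by 1.60 (SE 0.16) with the block, Klf6, a zinc-finger factor, by 1.07 (SE 0.13) and Dusp1, a MAP kinase phosphatase, by 0.97 (SE 0.12), each with edgeR adjusted p of 0.0241 to 0.036. Myc, Klf4 and Ier3 had log2 fold changes of -1.07, -1.31 and -1.14 and did not pass. In the antigen presentation list of 17 tested genes the median was -0.26, with -0.46 for Tapbp, -0.64 for H2-D1 and -0.46 for B2m. Mitotic genes of the G2/M list (50 tested) had a median of -0.31, with -0.48 for Bub1, -0.70 for Ube2c and -0.57 for Ckap5, and medians of -0.69, 0.0057 and 0.13 in batches 1, 2 and 3.

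Over all genes 0 members of these 4 lists passed without the block, and 3 immediate-early genes fell with it. Adjusted over the list alone with the block, 6 NF-kappaB and 4 antigen presentation genes fell, 4 immediate-early genes rose and 11 fell, and 0 G2/M genes passed. Camera adjusted p values were 0.00237 for both NF-kappaB and G2/M, 0.0347 for immediate-early and 0.0261 for antigen presentation genes (adjusted p = 0.649 with an estimated correlation for NF-kappaB and 0.882 for the other 3 lists). Fry as a directional test called none of these 4 lists. Its adjusted p values were 0.559 to 0.855 without the block and 0.448 to 0.666 with it. The G2/M median was 0.11 without PBS 1 (0.144) and -0.51 without PBS 3. The immediate-early median was 0.15 without PBS 2 (0.938), where camera still pointed down, -0.36 without BMP2 replicate 3 (0.361), -0.78 without BMP2 replicate 1 (0.0894) and -0.99 without BMP2 replicate 2, and its call was also lost with the stricter filter (0.0612) and the GC and length correction (0.053). The antigen presentation call was lost without BMP2 replicate 2 (0.0511), BMP2 replicate 3 (-0.13, 0.361), PBS 1 (0.0752) or PBS 2 (0.123), and its median was -0.49 without BMP2 replicate 1 and -0.13 with no filter. The NF-kappaB call was kept without each library, with medians of -0.28 without BMP2 replicate 3 and -0.29 without PBS 2, and -0.28 with no filter. Without batch 2, the adjusted p of Jun, Klf6 and Dusp1 with the block was 0.0611 to 0.226. Their log2 fold changes were then -1.65, -1.11 and -0.96, close to those over all batches. In all, 11 of the 34 tested lists passed camera in either fit, 0 did with an estimated correlation, and other splits of the 6 libraries gave up to 13 such lists.

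**Figure D3:**
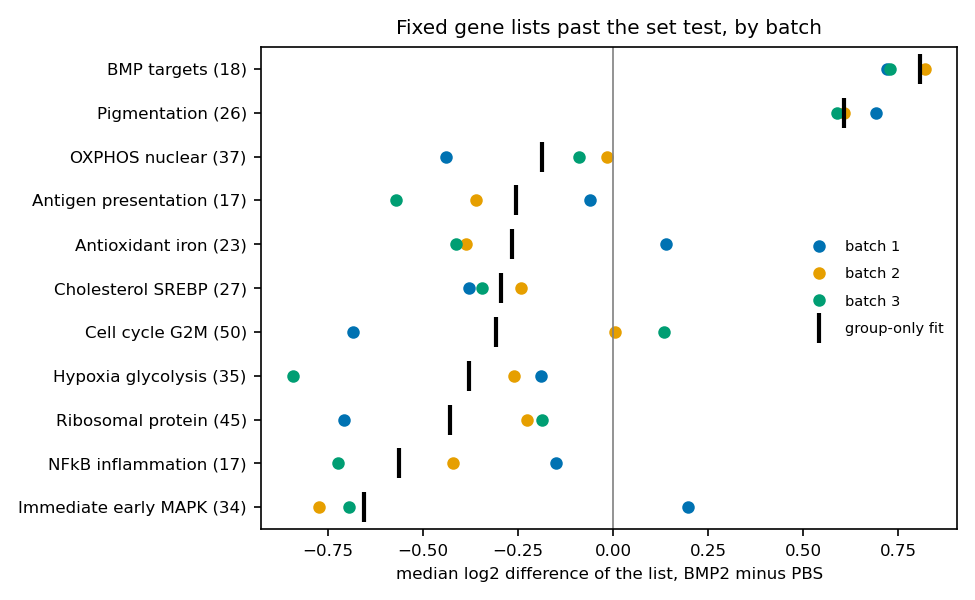
Median log2 difference, BMP2 minus PBS, of the 11 lists that passed camera, with colored points for the 3 batches, black bars for the fit without the block and the number of tested genes in brackets. The BMP target and pigmentation medians were above 0 in each batch, while the G2/M medians were -0.69, 0.0057 and 0.13.

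Among single genes outside the pseudogenes, the firmest differences were 2 that fell in both fits. Dync1li2, a light intermediate chain of cytoplasmic dynein (ENSMUSG00000035770, GRCm38 chromosome 8, 104417680 to 104443047), fell by 2.18 on the log2 scale (SE 0.20), from 193 ± 20.5 to 42.6 ± 6.3 CPM (edgeR adjusted p 0.0161). Lrp2, which encodes the endocytic receptor megalin (ENSMUSG00000027070, chromosome 2, 69424340 to 69586065), fell by 2.92 (SE 0.30), from 15.2 ± 2.2 to 2.01 ± 0.52 (0.0299). The adjusted p of Lrp2 was 0.0891 to 0.15 with any 1 library left out, and that of Dync1li2 was 0.0531 to 0.15 without BMP2 replicate 2, BMP2 replicate 3, PBS 2 or PBS 3, at log2 fold changes of -2.10 to -2.25. With near-identical genes summed, Lrp2 kept its log2 fold change of -2.92 at an adjusted p of 0.0538.

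No gene outside the pseudogenes rose in the edgeR fit without the block. Of those next in line and higher in all 3 batches, Rhod, a small GTPase of endosome motility, rose by 1.78 (SE 0.24) with the block, the phosphodiesterase gene Pde10a by 1.70 (SE 0.18), the glutaminyl cyclase gene Qpct by 1.44 (SE 0.20) and Map7d2, a microtubule-associated protein gene, by 2.27 (SE 0.23). Ass1, an enzyme of arginine synthesis that shares 43.1% of its 31-mers with other genes, was at 217 ± 73.9 against 48.1 ± 14.7 CPM and Dync1i1, a dynein intermediate chain gene, at 14.6 ± 6.5 against 1.46 ± 0.94, and these 2 did not pass in either fit. Among genes lower in all 3 batches, the calcium channel subunit gene Cacng4 fell by 3.78 (SE 0.51) with the block, Cdh13, an atypical cadherin, by 2.63 (SE 0.35) and the inositol transporter gene Slc5a3 by 1.32 (SE 0.20). These 7 genes had edgeR adjusted p of 0.0241 to 0.0482 with the block and of 0.0564 to 0.226 without batch 2, and Slc5a3 was at 0.0595 without batch 3. Without batch 2, the log2 fold changes of Rhod, Pde10a, Qpct and Map7d2 were 1.55, 1.83, 1.26 and 2.46. Those of Cacng4, Cdh13 and Slc5a3 were -3.79, -2.72 and -1.46. Rhpn1 had 0 counts in the BMP2 libraries and 130 in the PBS libraries, at least 14.8-fold lower against a floor of 3 counts in each library, and Nfix, a transcription factor gene, was at 2.66 ± 0.42 against 8.09 ± 1.95. Rhpn1 and Nfix did not pass in either fit. The retinol dehydrogenase genes Rdh9 and Rdh16f1 mirrored each other, with 9 against 329 and 285 against 0 counts in BMP2 and PBS libraries (Rdh16f1 at least 32.1-fold higher). Both are uncertain, since Rdh9 shares 71.8% and Rdh16f1 100% of its 31-mers and their sum had a log2 fold change of -0.20 with the block. Srp54b, a signal recognition particle gene, fell by 2.95 with the block but shares 89.9% of its 31-mers, and its family sum differed by 0.076.

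Over all 12929 genes, the edgeR quasi-likelihood test called 6 genes without the block (1 higher, 5 lower), with 696 genes at an unadjusted p under 0.05. With batch as a block it called 95 genes (48 higher, 47 lower), including all 6, with 2200 at an unadjusted p under 0.05. Leaving out batch 1, 2 or 3 from the blocked fit gave 531, 27 and 218 calls, of which 95, 23 and 87 were shared with the 95. Each of these fits held fewer libraries and residual degrees of freedom than the full blocked fit. Passing or failing there is therefore weak evidence on a single gene. Of the 33 named genes called with the block, 10 passed with each batch left out. These 10 include Rdh9 and Rdh16f1, whose levels are uncertain as given above. Some of the 33 were named because they passed with the block. Without the block, leaving out BMP2 replicate 1 gave 10 calls, and leaving out BMP2 replicate 2, BMP2 replicate 3, PBS 1, PBS 2 or PBS 3 gave 3, 2, 3, 2 and 2.

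The other 4 genes called without the block were pseudogenes whose 31-mers all occur in another gene, so their levels are uncertain. Gm5641, a copy of Hnrnpa3, had 1 count over the BMP2 libraries and 11179 over the PBS libraries, a ratio of 11604 with a counting interval of 2082 to 458362. Gm10443, a copy of Rps28, had 0 against 12628 counts and Gm26712, which matches Pyurf, 0 against 267, at least 1448-fold and at least 30.4-fold lower against the floor of 3 counts in each library. Rpl36a-ps2 had a log2 fold change of 2.90. Summed with their near-identical genes, the families of Hnrnpa3, Rps28, Pyurf and Rpl36a had log2 fold changes of -0.27 (SE 0.19), -0.42 (SE 0.22), -0.086 (SE 0.16) and -0.40 (SE 0.27), and 0 of 4 passed (edgeR adjusted p 0.883 to 0.934).

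**Figure D4:**
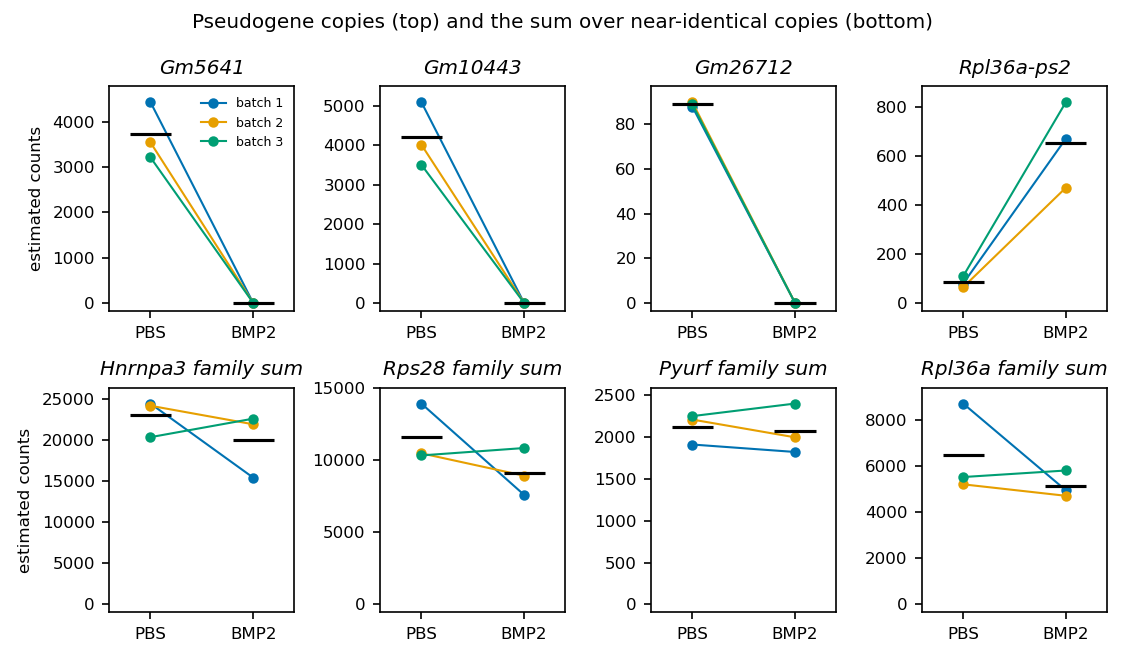
Estimated counts of 4 pseudogenes in each library (top) and of the sum over their near-identical genes (bottom), with lines joining the PBS and BMP2 cultures of a batch and black bars at the group means (n = 3). Gm5641, Gm10443 and Gm26712 had 1, 0 and 0 counts over the BMP2 libraries, while the family sums had log2 fold changes of -0.086 to -0.42.

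The lists of BMP pathway components, neural crest, invasion, G1/S and vasculogenic genes did not pass camera in either fit. In the BMP pathway list the receptor genes Acvr2b and Acvrl1 and the co-receptor gene Rgma had log2 fold changes of -1.36 (SE 0.71), -0.39 (SE 0.33) and -0.63 (SE 0.38). In the neural crest list, Jun fell with the block as given above, the receptor kinase gene Axl was at 84.6 ± 44.8 against 32.6 ± 7.3 CPM and Zeb2, a zinc-finger factor, at 138 ± 52.9 against 282 ± 173. Among invasion genes, the protease inhibitor gene Serpine2 and the metalloprotease genes Adamts4 and Adamts1 had log2 fold changes of 2.61 (SE 0.65), -0.63 (SE 0.19) and -0.75 (SE 0.28). In the G1/S list, Tyms, Ccne1 and Blm had values of 0.77, -0.52 and -0.40, and in the vasculogenic list, Epha2, Nrp2 and Nrp1 had -1.07, 0.48 and 0.50. The medians were -0.10 for the BMP pathway, -0.19 for neural crest, 0.12 for invasion, 0.14 for G1/S and -0.19 for vasculogenic genes, with camera adjusted p of 0.597 to 0.865. Adjusted over the list alone with the block, 1 neural crest gene rose and 2 fell, 3 invasion genes rose and 2 fell, and 0 genes of the other 3 lists passed. Of markers of other cell types, 7 leukocyte, 6 fibroblast, 5 epithelial, 3 endothelial and 0 erythroid genes were expressed highly enough to test, and 0 of them passed over all genes in either fit. Adjusted over the list alone with the block, 1 leukocyte gene rose, the lysozyme gene Lyz2, named after its values were seen, with a log2 fold change of 1.63 and an edgeR adjusted p of 0.0267. The leukocyte, fibroblast and epithelial medians were 0.14, -0.12 and 0.41 (camera adjusted p 0.652, 0.597 and 0.645), and the endothelial and erythroid lists were too small for the test. In batches 1, 2 and 3 the medians were 1.04, -0.50 and 0.18 for leukocyte, 0.14, -0.43 and -0.41 for fibroblast and 1.27, 0.29 and -0.12 for epithelial markers.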

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

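The summing of near-identical genes, the alternatives run together with the block and the leaving out of batches were chosen after the data were seen. The replicate block called 95 genes (48 higher, 47 lower) in place of 6 (1 higher, 5 lower), and 31 of the 84 named genes tested gained a call with it, as 33 did with DESeq2 and 17 with no filter, both without the block. Some of the 84 were named because they passed with the block, so their gain with it was fixed in advance. The 31 of 84 therefore does not measure the effect of the block. The same 11 lists passed camera in both fits, while the directional fry test called the pigmentation list only with the block (adjusted p 0.0467 against 0.559). That test called no other list in either fit, and its next lowest adjusted p with the block was 0.103, for cholesterol genes. With no filter the counts were 35 (19 and 16), and 500 (223 and 277) with the block. DESeq2 called 130 (62 and 68), and 653 (241 and 412) with the block, and the GC and length correction with the block called 114 (57 and 57). The stricter filter left 0 higher genes, quantile normalization gave 2 higher, and summing gave 1 gene (0 higher, 1 lower). Leaving out 1 library gave 2 to 10 genes (0 to 5 higher, 2 to 5 lower) and 7 to 10 lists. Leaving out 1 batch from the blocked fit gave 27 to 531 genes (9 to 223 higher, 18 to 308 lower). With an estimated correlation 0 lists passed in either fit, at BMP target medians of 0.81 and 0.73 with adjusted p of 0.882 and 0.837. The BMP target list otherwise kept its direction and its call, with medians of 0.24 to 2.10 without the block. Without single libraries the G2/M median ran from -0.51 to 0.11 (without PBS 1), that of oxidative phosphorylation from -0.29 to 0.00639 (without PBS 1), that of cholesterol genes from -0.65 to 0.11 (without PBS 3) and Bambi from -0.40 to 0.35 (without PBS 1). In the blocked fit, leaving out a batch moved the G2/M median between -0.45 and 0.0665, and calls were lost for G2/M without batch 1 (0.0665, adjusted p 0.655), oxidative phosphorylation without batch 1 (-0.052, adjusted p 0.563), antioxidant genes without batch 2 (-0.079, 0.272) or 3 (-0.15, 0.462), immediate-early genes without batch 2 (-0.44, 0.297) and antigen presentation without batch 2 (-0.34, 0.0978) or 3 (-0.37, 0.088). The other lists kept their calls there, with medians of 0.65 to 1.33 for BMP targets, 0.55 to 0.70 for pigmentation, -0.57 to -0.19 for hypoxia, -0.49 to -0.20 for ribosomal proteins, -0.76 to -0.27 for NF-kappaB and -0.33 to -0.24 for cholesterol. Fewer samples were fitted there, and the cause was not tested further; nor was it for the other settings. The pseudocounts of 0.1 and 5 and limma without a trend were not run, since the table holds estimated counts. At this depth and the spread of the blocked fit, 2-fold changes were recovered in 0% of simulated genes without the block and 63% with it. Batch differences were built into those counts, so the gain is no evidence for the block in these data.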

Other observations

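The test of the pseudogene copies, those of the blocked calls summed with a copy and of the 31-mers of all blocked calls, the summing for the ribosomal list and the fit of batches 2 and 3 alone were chosen after the results were seen, as were the genes named here.

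Among lists that did not pass camera, single members moved with batch as a block. Col4a1, a collagen chain of basement membranes, fell by 2.05 (SE 0.22), and of 21 matrix genes tested, 1 rose and 6 fell adjusted over the list alone, with Col18a1 at 3.51 and Col4a2 at -1.55. Skil, a negative regulator of SMAD signalling in the list of TGF-beta targets, rose by 1.19 (SE 0.15). The survival gene Bcl2l1 rose by 0.99 (SE 0.13), and of 27 apoptosis genes 3 rose and 1 fell adjusted over the list alone, with Bcl2 at 1.11 and the BH3-only gene Bbc3 at -1.35. The chemokine gene Cxcl10 fell by 2.49 (SE 0.32). The edgeR adjusted p values over all genes with the block were 0.0241 for Col4a1, 0.036 for Skil and Cxcl10 and 0.0363 for Bcl2l1. Without batch 2 only Cxcl10 of these 4 passed (0.0438), and without the block none did (0.33 to 0.67). The log2 fold changes of Col4a1, Skil and Bcl2l1 without batch 2 were -2.11, 1.20 and 0.88. The interferon list had medians of 1.23, -0.49 and -0.019 in batches 1, 2 and 3, and its median over all libraries was 0.17 (camera adjusted p 0.386). The leukocyte markers were at 1.04, -0.50 and 0.18 in the same batches, and the epithelial markers at 1.27, 0.29 and -0.12.

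Near-identical copies are a candidate explanation for the calls at pseudogenes, since all 4 pseudogenes called without the block lost the call when summed with their families, with 0 families past the threshold. Of the 95 blocked calls, 17 shared at least 50% of their 31-mers and 15 of these had a copy to be summed with, of which 1 kept the call, while their median absolute log2 fold change went from 4.15 to 0.26. Of 5 calls that shared less and were summed, 3 kept the call, while Pdcd5 (-1.29 to -0.91, edgeR adjusted p 0.0529) and Ubald2 (-1.10 to -0.62, 0.142) lost it. A difference in how reads were divided between copies in the 2 groups may thus underlie the 14 lost among the 15, although adding an abundant copy would also dilute a true change of a small one, and whether both groups were quantified alike stays open. The number of calls kept with copies summed, the test set beforehand for all 95, decides nothing, since 75 have no copy to add. The 95 shared a median of 0.535% of their 31-mers, against 1.14% over all tested genes, which argues against copies as the cause of most of the calls. A median cannot speak to a minority, and 17.9% of the calls shared at least 50%, against 7.66% of tested genes.

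The higher pigmentation list was weighed against gene length and GC content and against PBS 1. After the correction with the block it kept 92.8% of its blocked median (camera adjusted p 4.22e-11), and without PBS 1 it kept 80.6% of its median (7.65e-06). Both tests argue against these as the whole cause. An effect of BMP2 on the melanocyte program stays open as a hypothesis, which the same transcripts in new cultures, with and without a blocked BMP receptor, would test. With an estimated correlation the list did not pass (adjusted p = 0.882 with an estimated correlation).

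The lower oxidative phosphorylation list may come largely from PBS 1, the library that stood apart, and the lower ribosomal protein list in part. Without PBS 1 the ribosomal and oxidative phosphorylation lists kept 22.9% and -3.41% of their medians, below the 25% set beforehand. That fit had no block and kept the BMP2 culture of batch 1, whose deviations correlated with those of PBS 1 (0.51). Batches 2 and 3 alone with the block gave a ribosomal median of -0.20 (camera adjusted p 0.000143), against -0.38 over all batches. For oxidative phosphorylation the values were -0.052 (0.563) and -0.18. With 35 of 45 ribosomal genes lower in all 3 batches, part of that difference may lie outside PBS 1. Over all batches with the block, each list had an adjusted p = 0.837 with an estimated correlation. The correction for length and GC content kept 95.8% and 103% of the blocked medians, and summing copies kept 104% of the ribosomal one, which argues against both as the cause. What set PBS 1 apart, in culture or in the library, cannot be read from these data, and an effect of BMP2 stays open.

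The 6 libraries can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 6 genes without the block and was the only 1 of the 10 to give as many, and the highest other gave 0. Of the 6, 4 were the pseudogene copies, and with copies summed the real split gave 1 gene. The contrast may thus rest in part on how reads were divided between copies. The other splits were not run with copies summed. Of the 4 splits that part the libraries of all 3 batches, also too few, only 1, the real split, gave its 95 genes with the block, and the highest other gave 0. For the lists, 4 of the 10 splits gave as many as the real 11, and the highest other gave 13. Of the 4 that part all batches, 2 gave as many lists, the real one included. For the BMP target median, 3 of the 10 gave one as large as 0.81, and the highest other was 1.10. Both larger medians came from splits that keep a batch together, and of the 4 that part all batches the real one was the largest, with 0.11 to 0.67 for the others.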
